A study of Mus musculus with 2 samples.

How the data were processed

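RNA was measured in bone marrow-derived macrophages, cells grown from mouse marrow with macrophage colony-stimulating factor (M-CSF). The labels give a 5-day culture with 20 ng/ml M-CSF and extraction of total RNA with TRIzol. There are 2 samples. The KO sample comes from Spp1-floxed mice that carry a Cre recombinase at Lyz2, a myeloid driver, and the WT sample comes from floxed mice without the Cre. Each genotype has 1 library, so the groups follow directly from the sample titles and genotypes. How many animals or cultures fed each library, their sex, and which part of Spp1 is floxed are not given in the sources used here.

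The values used are the authors' deposited FPKM (fragments per kilobase of gene, scaled to the mapped fragments of the library), 1 table for the whole series with gene symbols in its rows. The submitters' processing notes name RSEM, DESeq2 and the mouse build mm10, with no role or version. The aligner, the gene annotation and any filter are not given in the sources used here. The table has 4 columns of values, of which 2 carry the titles of the samples. The other 2 columns, headed WT-CM and KO-CM, match no sample and were not used. What they hold is not given.

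The table has 42396 rows. Of these, 2379 carry a number added to a symbol that stands in the table more than once, and 1766 symbols have more than 1 row. Why a symbol has several rows is not given. Reads that fit several copies of a gene can be shared out, dropped or assigned differently in different libraries, and for such symbols a difference between libraries can come from that step. For each symbol the row with the highest mean FPKM was kept, which left 40017 symbols. Symbols with several rows are named as such wherever they appear, since their values are uncertain.

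FPKM values are relative within a library: a rise of 1 very abundant gene lowers all others. The summed FPKM were 422004 in the KO library and 425814 in the WT library. Depth was read from the lowest values, where FPKM moves in whole-read steps. Over 3152 symbols whose 2 values sum to below 0.3 FPKM, a WT to KO depth ratio of 1.308 turned 78.7% of the value pairs into ratios of whole numbers up to 10 within a tolerance of 0.0001. A ratio set wrong by 5% did so for 10.2%. The ratio of 1.308 was the most common one among these symbols, taken to be 1 read against 1 read. The contrast with a ratio wrong by 5% cannot tell it from simple fractions of it. With exon lengths of single-transcript genes from GENCODE M21 on GRCm38 (the mm10 build), the steps gave an estimated depth of 34.8 M (mega) reads or fragments for KO and 45.5 M for WT. This estimate rests on the 65 of 360 such genes in the most filled bin and on annotated lengths that need not be those the authors used. At these depths, 1 read in a gene of 1 kb is worth 0.0288 FPKM in KO and 0.0220 FPKM in WT. The reads themselves were not used here, so no counting interval is given.

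Differences were computed as log2(FPKM + 1), KO minus WT, a scale that understates the change of genes with low values. Folds printed beside them are ratios of FPKM. Symbols with a mean FPKM of at least 1 over the 2 libraries were kept, 10536 in all. A symbol was counted as higher or lower in the KO library when its difference was at least 1 in size. This is a rule of size, without a test: no p-value, standard error or count of significant genes can be had from 1 library per genotype. For each of 52 gene lists, the median difference over its members past the filter was set against 10000 random lists of the same size matched on mean FPKM in 20 bins (seed 1). A list of at least 5 such genes was said to stand apart when its median lay below the 2nd or above the 98th percentile of the random lists. The random lists treat genes as independent, which genes of 1 pathway are not, so the percentiles describe these libraries and are no measure of error. A single gene's difference was ranked among the 500 symbols nearest to it in mean FPKM.

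The rule for named genes took Spp1 and Lyz2, the 12 largest differences in each direction without predicted genes, clone names and pseudogenes, and up to 4 members of each list with the largest differences in size. Any other gene lies outside this rule and counts as chosen after its values were seen, also where the text does not repeat this. The values of some single genes are not reported here. The lists, thresholds, named-gene rule and main alternatives were fixed before the data were examined. The alternatives were pseudocounts of 0.1 and 5 FPKM, 4 other scalings or centrings, summing the rows of a symbol, no filter or a mean FPKM of at least 5, thresholds of 1.5-fold and 3-fold, and a list's mean in place of its median. Leaving out symbols with several rows, keeping only protein-coding symbols with 1 row, counting rows as deposited and removing trends with gene length or GC content were added after seeing the data. The alternatives for lists used 2000 random lists.

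The counting and list steps were tested on data simulated with whole reads at the real genes' levels. The 2-fold rule took 2% of 50 genes changed 1.5-fold up, 98% of 50 changed 3-fold up, 74% of 50 set to 0.333 of their level, 100% of 50 changed 8-fold and 0% of 10336 unchanged genes. The simulation held counting noise only, with no spread between cultures. Gene positions, lengths and biotypes came from GENCODE M21 and RefSeq tables, joined by symbol; 97.0% of the symbols past the filter had a length and GC value. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.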

Results

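The study profiled RNA from mouse bone marrow-derived macrophages to ask what loss of SPP1 (osteopontin, a secreted phosphoprotein) does to the macrophage. The comparison is between 1 KO library, from floxed mice with Lyz2-driven Cre, and 1 WT library, from floxed mice without it. Both cultures had 5 days of M-CSF at 20 ng/ml. The estimated depth was 34.8 M reads or fragments for KO and 45.5 M for WT. There are no replicates, so every difference below is a difference between 2 libraries, and no spread between cultures is known. Both libraries had a similar number of symbols at 1 FPKM or more, 10524 in KO and 10547 in WT. Across the 10536 symbols with a mean FPKM of at least 1, the log2(FPKM + 1) values correlated with Pearson r = 0.98 and Spearman rho = 0.981. These are correlations across genes, which are not independent replicates. The median difference was -0.01, and 95.6% of symbols lay within 1.5-fold on the FPKM + 1 scale.

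The targeted gene was nearly absent from the KO library. Spp1 (ENSMUSG00000029304.14, chromosome 5, 104435118 to 104441050, plus strand, GRCm38) stood at 11.3 FPKM in KO and 4006 FPKM in WT, 353-fold lower, a difference of -8.34. KO held 0.283% of the WT level. In WT it was number 10 of all symbols by FPKM, and in KO it was number 5150. The values are for the whole gene, so they do not show which exons carry the remaining reads. The expressed genes within 2 Mb of Spp1 had a median difference of -0.03 (15 genes). Among the neighbours fixed as a list, Pkd2 stood at 4.96 in KO and 4.07 FPKM in WT, and Abcg2 at 6.34 and 6.14 FPKM, a median difference of 0.14 over these 2 genes. The bone-matrix relatives of Spp1 beside it, Ibsp, Mepe, Dmp1 and Dspp, were below the filter in both libraries.

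Lyz2, the lysozyme gene that drives the Cre (chromosome 10, 117277331 to 117282321, minus strand), was the most abundant symbol singled out by the rule. It stood at 13539 FPKM in KO and 29499 FPKM in WT, 45.9% of the WT level (difference -1.12). Lyz2 alone took 3.21% of the summed FPKM in KO and 6.93% in WT. Its neighbouring paralog Lyz1, with which it can share reads, was also lower in KO, at 13.6 against 25.1 FPKM (-0.84). The 19 expressed genes within 2 Mb of Lyz2 had a median difference of 0.04.

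By the 2-fold rule, 130 symbols were higher and 50 lower in the KO library. Of these, 43 of the higher and 30 of the lower symbols had several rows in the table, although such symbols made up only 3.39% of those past the filter. Short RNAs with 1 row (microRNA, small nucleolar and transfer RNA names, for example) made up another 20 of the higher and 13 of the lower symbols. Among the 9544 protein-coding symbols with 1 row, an alternative chosen after seeing the data, 53 were higher and 5 lower. Of these 53, 29 belong to the interferon lists described next. The 5 lower genes were Spp1, Lyz2, F13a1, Serping1 and Dcn.

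**Figure D1:**
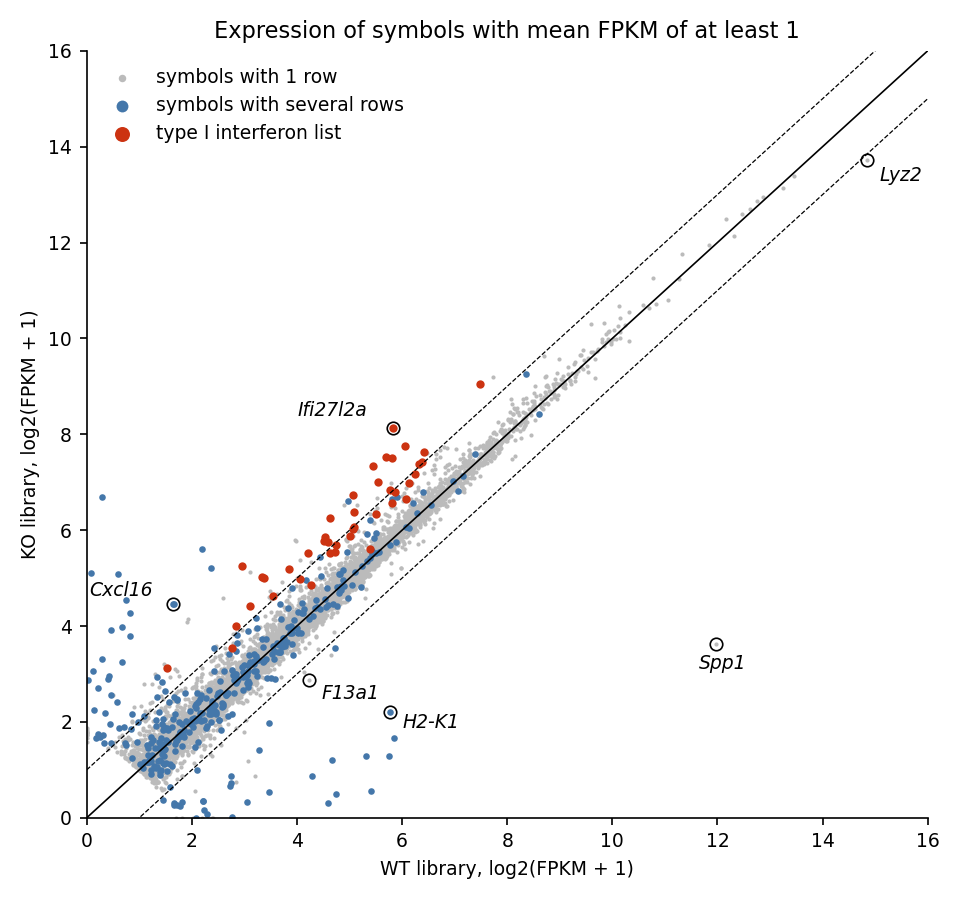
Each point is a symbol with a mean FPKM of at least 1, placed by log2(FPKM + 1) in the WT library (x axis) and the KO library (y axis); red marks the type I interferon list, blue the other symbols with several rows, and dashed lines a difference of 1 in either direction. Spp1 lies far below the diagonal at 4006 FPKM in WT and 11.3 FPKM in KO, and the interferon genes lie above it. Most other points with a difference of at least 2 in size are symbols with several rows.

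Interferon-response genes were higher in the KO library, and this was the broadest difference between the 2 libraries. All 42 measured genes of the type I interferon list, antiviral genes induced by interferon alpha and beta, were higher in KO, 26 of them by the 2-fold rule. The list's median difference was 1.15, above all 10000 matched random lists, whose 2nd to 98th percentiles ran from -0.05 to 0.07. The largest differences belonged to Ifi44, at 37.3 FPKM in KO and 6.76 in WT (5.51-fold), and Ifi27l2a, at 278.0 and 56.1 FPKM (4.95-fold). Ifit2, which binds viral RNA, stood at 160.5 and 42.6 FPKM, and the ubiquitin-like protein gene Isg15 at 182.8 and 50.9 FPKM. Among further members, chosen after their values were seen, the transcription factor gene Irf7 was 3.28-fold higher and Bst2, which tethers budding virus, 2.97-fold higher. The smallest difference was that of Irf9, 47.9 in KO against 41.2 FPKM in WT. Symbols with several rows made up 4 of the 42 (Ifi203, Ifi204, Slfn5 and Slfn8).

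Genes of the interferon gamma list were also higher, 21 of 21 in direction and 6 by the 2-fold rule, with a median difference of 0.78, above all 10000 random lists. Ly6a, a surface protein gene known as Sca-1, stood at 16.8 FPKM in KO and 2.81 in WT (5.97-fold). The GTPase genes Gbp6 (6.65 against 2.02 FPKM) and Iigp1 (4.37 against 1.37 FPKM) followed, with Igtp at 2.73 against 0.631 FPKM, a symbol with several rows. These genes overlap in their induction with the type I list. The smallest difference in the interferon gamma list was that of Ciita, 8.05 FPKM in KO against 7.86 in WT, chosen after its values were seen. Of that list's 29 genes, 21 passed the filter. Together the 2 lists hold 62 expressed genes, of which 32 were higher by the 2-fold rule. The interferon transcripts looked at were below 1 FPKM. Ifnb1 stood at 0.374 FPKM in KO and is listed at 0 in WT, and Ifna4 and Ifng are listed at 0 in both. The Ifnb1 value in KO lies above the estimated 0.0288 FPKM that 1 read in a gene of 1 kb is worth there. The receptor genes Ifnar1 (25.1 in KO, 25.7 FPKM in WT) and Ifnar2 (48.3 and 45.4 FPKM) were close to equal. These interferon and receptor genes were chosen after the list values were seen.

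Sex-linked transcripts differed along with the interferon genes. Xist, made from the inactive X chromosome of female cells, and Y-linked transcripts were present in both libraries. Xist stood at 45.7 FPKM in KO and 58.5 in WT, while Ddx3y (6.50 and 3.30 FPKM), Eif2s3y (9.90 and 5.31 FPKM) and Uty (2.32 and 1.13 FPKM) were higher in KO. The sum of 4 Y-linked genes was 20.6 FPKM in KO and 11.4 in WT. The list's median difference was 0.64 over 5 genes, with Xist opposite to the other 4. Some cell-type markers differed along with the interferon genes too. Monocyte markers had a median of 0.29 (99.98th percentile), but F13a1 in that list went the other way (-1.35). Macrophage identity genes had a median of -0.07 (0.26th percentile), with a mean of -0.02 inside the random range. The stromal genes Dcn (1.46 against 4.23 FPKM) and Bgn (1.84 against 3.18 FPKM) were lower in KO.

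Chemokines that attract T cells, the cells named in the study's title, differed one by one. Ccl5 stood at 22.9 FPKM in KO and 5.00 in WT (4.57-fold, 1.99) and Cxcl10, a CXCR3 ligand, at 23.7 and 13.4 FPKM (1.77-fold, 0.78). Ccl4 stood at 24.97 and 17.7 FPKM, and Ccl3 was level at 21.85 and 21.996 FPKM. Cxcl16 showed 20.9 against 2.12 FPKM, but has several rows. Over these 5 genes, the only ones of the list's 10 past the filter, the median difference was 0.78, above all 10000 random lists. That median is the value of Cxcl10, which also stands in the interferon gamma list and sets the median there. The other CXCR3 ligands were near the floor, with Cxcl9 at 0.158 FPKM in KO and 0.0606 in WT, and Cxcl11 at 0.0717 FPKM in KO and listed at 0 in WT. Among chemokines for monocytes and neutrophils, Ccl2 (9.50 against 4.86 FPKM) and Ccl12 (3.60 against 1.89 FPKM) led a list with a median of 0.33 over 5 genes, at the 99.3rd percentile; with no filter on low values the median was -0.05 over 14 genes. None of the 6 chemokines for Th2 and regulatory T cells passed the filter. Chemokine receptors had a median of 0.13 over 8 genes, inside the random range, with Cx3cr1 at 38.2 and 29.4 FPKM and Ccr2 at 24.3 and 20.1 FPKM.

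**Figure D2:**
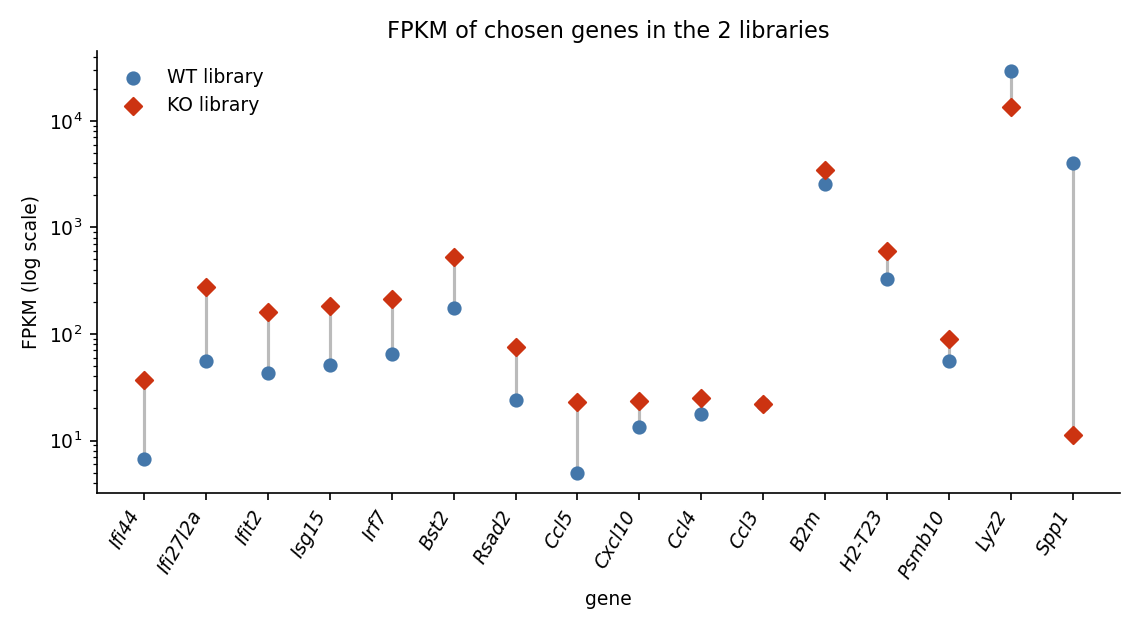
FPKM on a log axis in the KO library (diamonds) and the WT library (circles) for interferon-response, chemokine and MHC class I genes, Lyz2 and Spp1; each point is 1 library and no error bar can be drawn. Ccl5 stands at 22.9 in KO and 5.00 in WT, the Ccl3 points overlap at 21.85 and 21.996, and Spp1 spans 11.3 to 4006.

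Genes that load and present peptides on MHC class I, the display read by CD8 T cells, had small differences, most of them higher in KO. The list's median difference was 0.55 over 16 genes, above all 10000 random lists, and 14 of the 16 were higher in direction. By the 2-fold rule 1 was higher (Tapbp) and 1 lower (H2-K1, the largest difference in the list), and both have several rows. B2m, the shared light chain, stood at 3456 FPKM in KO and 2578 in WT (1.34-fold). The proteasome subunit gene Psmb10 stood at 90.4 and 55.2 FPKM, and the transactivator gene Nlrc5, also in the interferon gamma list, at 16.6 and 10.7 FPKM. These 3 were chosen after their values were seen because the genes with the largest differences all have several rows. Those are H2-K1 (3.63 against 53.4 FPKM), Tapbp (21.1 against 2.14 FPKM), H2-Q4 (17.0 against 8.38 FPKM) and H2-T23 (606.9 against 326.9 FPKM). Tap1, Tap2, Psmb8 and Psmb9, with 4 rows each, were below 1 FPKM in both libraries. MHC class II genes had a median of 0.06 over 8 genes, at the 78.6th percentile, with Ctss at 5737 and 4574 FPKM, Ifi30 at 56.3 and 43.3 FPKM, H2-Aa at 2.75 and 1.502 FPKM, and H2-DMb1 at 11.4 and 13.9 FPKM; Ifi30 and the H2 genes have several rows.

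Ligands that act on T cells showed small differences in both directions. Costimulatory ligands had a median of 0.09 over 12 genes, at the 94.9th percentile. Il15, a cytokine for CD8 T and NK cells, stood at 26.1 FPKM in KO and 18.2 in WT, Cd40 at 3.34 and 1.797 FPKM, and Il27 at 2.10 and 1.07 FPKM, while Cd80 stood at 4.38 and 5.43 FPKM. Inhibitory molecules had a median of -0.10 over 15 genes, at the 1.1st percentile, with 10 lower and 5 higher in direction. Its largest differences went both ways: Lgals9 (galectin-9) stood at 210.5 in KO and 110.0 FPKM in WT, Cd274 (PD-L1) at 20.3 and 15.6 FPKM, Entpd1 (CD39) at 51.5 and 64.2 FPKM, and Nectin2 at 3.48 and 4.55 FPKM. The list's mean was -0.01, at the 27.9th percentile.

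Inflammatory cytokines and NF-kB regulators did not stand apart, in contrast to the interferon genes. The inflammatory list had a median of 0.08 over 13 genes (95.6th percentile). Within it, Acod1 stood at 7.94 in KO and 4.47 FPKM in WT, Tnfsf10 (TRAIL) at 2.67 and 1.35 FPKM, Fpr2 at 7.26 and 4.72 FPKM, and the interleukin-1 antagonist gene Il1rn at 21.7 and 15.5 FPKM. Tnf, which has several rows, Il6 and Nos2 were below 0.2 FPKM in both libraries. NF-kB regulators had a median of -0.03 over 17 genes, with Bcl3 at 10.5 and 14.4 FPKM. Toll-like and cytosolic sensors had a median of 0.15 over 25 genes, above the random range, led by Tlr3 (6.002 against 4.03 FPKM), Cgas (7.02 against 5.17 FPKM) and Tlr9 (54.8 against 42.0 FPKM); none of them passed the 2-fold rule. Immediate early genes had a median of 0.02 over 16 genes and heat shock genes 0.04 over 8.

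Macrophage identity genes had a median of -0.07 over 26 genes, at the 0.26th percentile, with 15 lower and 11 higher in direction. The growth factor receptor gene Csf1r stood at 851.8 in KO and 834.7 FPKM in WT, and Adgre1 (F4/80) at 520.1 and 473.2 FPKM, both chosen after their values were seen. The list's random range was -0.05 to 0.10, and its mean of -0.02 lay inside the random range. Its largest differences were Lyz2, Siglec1 (192.9 against 87.9 FPKM), the high-affinity IgG receptor gene Fcgr1 (190.2 against 99.2 FPKM) and Lyz1. Phagocytosis and scavenger receptors had a median of -0.04 over 23 genes, at the 5.06th percentile. Among them Fcgr4 stood at 207.9 and 114.2 FPKM, Cd300lf at 25.8 and 15.8 FPKM, and Colec12 was lower in KO at 32.7 and 54.0 FPKM. Fcgr1 and Fcgr4 also stand in the interferon gamma list. Lipid-associated macrophage genes, a group to which Spp1 itself belongs, had a median of 0.08 over 24 genes and did not stand apart; Apoc1 was lower in KO (0.525 against 1.78 FPKM), Cd36 stood at 234.0 and 201.1 FPKM, and Trem2, with several rows, at 12.2 and 9.10 FPKM. Osteopontin receptors had a median of 0.03 over 9 genes, with Itgb7 at 12.7 and 8.03 FPKM, Itgav at 32.1 and 24.7 FPKM, and Itgb3 at 10.2 and 12.7 FPKM.

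Alternative activation genes had a median of -0.12 over 14 genes, at the 0.48th percentile, with 9 lower and 5 higher in direction. Ear2 stood at 2.89 FPKM in KO and 5.41 in WT. Clec10a stood at 0.825 and 5.75 FPKM but has several rows, and without such symbols the median of -0.08 lay inside the random range. Folr2 (46.7 against 37.6 FPKM) and Chil3 (2.34 against 1.66 FPKM) went the other way. Monocyte markers had a median of 0.29 over 10 genes, above the random range, with Ms4a4c at 53.4 and 14.7 FPKM, S100a6 at 153.6 and 97.7 FPKM and Plac8 at 1.84 and 0.588 FPKM. In the same list F13a1, the coagulation factor XIII A chain, was lower in KO at 6.36 against 17.8 FPKM (-1.35). Complement genes had a median of -0.10 over 11 genes, at the 2.35th percentile; Serping1, the C1 inhibitor gene, was lower in KO (1.01 against 3.27 FPKM), whereas C3 stood at 59.6 and 46.5 FPKM. Matrix genes (-0.02 over 17), angiogenic factors (0.03 over 13), the TGF-beta pathway (-0.03 over 12) and osteoclast genes (-0.08 over 7) lay inside their random ranges. Their largest differences were Plau (60.9 against 37.6 FPKM), Kdr (19.3 against 12.7 FPKM), Skil (17.4 against 12.02 FPKM) and Dcstamp (3.999 against 2.40 FPKM), each higher in KO.

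Metabolic lists differed by small amounts. Cholesterol synthesis genes had a median of 0.18 over 22 genes, with 20 higher in KO, above all 10000 random lists; Insig1 stood at 44.9 and 34.2 FPKM, Fdps at 42.6 and 33.2 FPKM and Hmgcs1 at 41.5 and 33.1 FPKM. Nuclear genes of oxidative phosphorylation had a median of 0.17 over 30 genes, with 25 higher. The largest differences were Ndufs3 (42.5 against 20.8 FPKM), which has several rows, Ndufa2 (55.1 against 29.5 FPKM) and Cox6c (79.9 against 50.2 FPKM). Cytosolic ribosomal protein genes had a median of 0.22 over 30 genes, with 24 higher, among them Rps29 (80.0 against 40.8 FPKM) and Rps19 (397.2 against 270.4 FPKM). Many of these genes are short, and across all expressed symbols the difference ran against gene length with rho = -0.16. With the length trend removed the medians were 0.14 for oxidative phosphorylation and 0.19 for ribosomal proteins, both still above the random ranges. Apoptosis and p53 targets had a median of 0.16 over 16 genes (Bcl2a1b at 78.6 and 43.4 FPKM) and the unfolded protein and integrated stress response 0.12 over 18 (Ddit3 at 22.6 and 15.4 FPKM). Hypoxia genes had a median of -0.13 over 15 genes, at the 1.11st percentile, with 12 lower, such as Ndrg1 (29.3 against 37.0 FPKM) and Mxi1 (13.4 against 17.5 FPKM). Glycolysis (-0.02 over 20), cholesterol efflux (0.02 over 10), lysosome (0.06 over 26), NRF2 targets (-0.07 over 13), PI3K-AKT components (0.02 over 20) and cell cycle genes (-0.02 over 36) lay inside their random ranges. Mki67 stood at 29.7 and 37.0 FPKM, and Hmox1 at 180.6 and 213.4 FPKM. The mitochondrial ribosomal RNAs mt-Rnr1 (205.6 and 191.6 FPKM) and mt-Rnr2 (190.4 and 202.1 FPKM) were close. Housekeeping controls had a median of -0.03 over 13 genes. Gapdh, which has many pseudogene copies, stood at only 2.20 FPKM in KO and 3.59 in WT, next to 528.9 and 588.8 FPKM for the glycolytic gene Aldoa.

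In all, 40 lists had at least 5 genes past the filter, and 13 stood higher and 4 lower, where 1.6 would lie outside the bounds if genes were independent. Of these 17 lists, 8 lost that place under at least 1 alternative: monocyte and neutrophil chemokines, the unfolded protein response, T cell inhibitory molecules, alternative activation, hypoxia, toll-like sensors, macrophage identity and sex-linked genes.

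**Figure D3:**
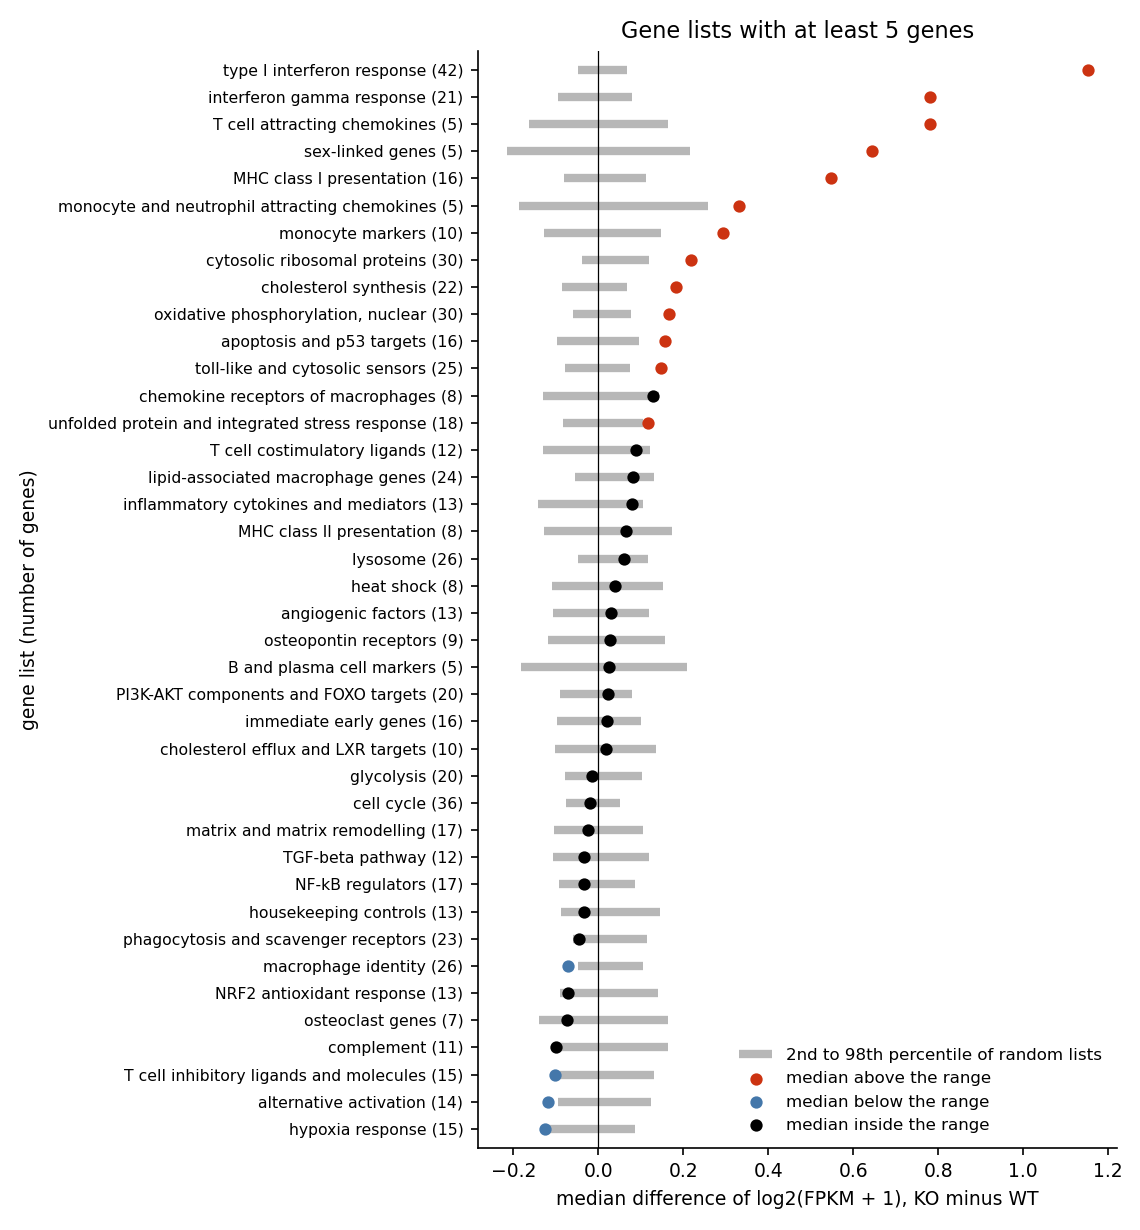
Median difference of log2(FPKM + 1), KO minus WT (x axis), for the 40 gene lists with at least 5 measured genes (y axis, number of genes in brackets); grey bars span the 2nd to 98th percentile of 10000 matched random lists. The type I interferon list lies at 1.15 and the MHC class I list at 0.55, while the lists below 0 reach -0.13.

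Of 118 markers of other cell types in the table, dendritic cells aside, 18 reached a mean of 1 FPKM, none was higher and 1 lower by the 2-fold rule. The lower one was Dcn, a fibroblast gene, at 1.46 FPKM in KO and 4.23 in WT; Bgn, also stromal, stood at 1.84 and 3.18 FPKM. Lists of neutrophil, T and NK cell, mast cell, eosinophil, erythroid and endothelial markers had fewer than 5 genes past the filter. Among them, Il7r stood at 145.9 FPKM in KO and 134.3 in WT, Csf3r at 41.03 and 43.2 FPKM, S100a8 at 2.86 and 1.52 FPKM, Cd4 at 8.65 and 10.8 FPKM, Kit at 3.999 and 5.23 FPKM, Siglecf at 7.17 and 6.25 FPKM, Itga2b at 4.05 and 3.58 FPKM and Vwf at 12.9 and 13.9 FPKM. B cell markers had a median of 0.03 over 5 genes, with Blnk at 95.6 and 93.9 FPKM and Igkc at 4.41 and 2.27 FPKM. The T cell gene Cd3e is listed at 0 in both libraries. The B cell gene Cd79a stood at 0.546 FPKM in KO and 0.220 in WT. Cd3e and Cd79a were chosen after their values were seen. In the dendritic cell list 4 genes passed, and its only large difference was Bst2, which also stands in the type I interferon list.

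The most extreme differences rest mostly on symbols with several rows. Of the 24 genes with the 12 largest differences in each direction, 23 have several rows, and Spp1 is the exception. In KO the ribosomal gene Rps28 stood at 102.7 FPKM against 0.223 in WT, Gstp1 at 33.4 against 0.0591 FPKM and Supt4a at 33.0 against 0.503 FPKM. Rnf181, Slc25a11, Spag7, Ppp1ca, Mir7115, Gps2, Sf1, Pold4 and Arrb2 made up the rest of the higher set, with differences of 2.85 to 3.80. On the lower side, Ranbp1 stood at 0.473 FPKM in KO and 41.4 in WT, Vamp8 at 1.43 and 52.6 FPKM, and Rnf5 at 0.235 and 22.96 FPKM. Cdk2ap2, Atp6v1c1, Ctdnep1, H2-K1, Atp6v1e1, Brd2, Nrbf2 and Gdpd1 followed, with differences from -4.25 to -2.73. When the rows of a symbol were summed, Brd2 moved from -2.93 to -0.26, H2-K1 from -3.55 to -2.35 and Atp6v1e1 from -3.46 to -2.47. The values of these 23 symbols are uncertain.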

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

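With 1 library per genotype, no replicate could be left out. No paired analysis was possible because each genotype has 1 library and no result comes from a test. Leaving out symbols with several rows, keeping protein-coding symbols, counting rows as deposited and removing length or GC trends were chosen after seeing the data. The interferon and MHC class I lists kept their direction and their place above the random lists under every alternative run. Their values (medians, and the mean as 1 alternative) ranged from 1.01 to 1.23 for type I interferon, 0.53 to 0.87 for interferon gamma and 0.39 to 0.58 for MHC class I. The list of T cell chemokines falls to 4 genes without symbols with several rows, too few for a percentile. Of the named genes' differences under the alternatives, 1271 stayed within 1.5-fold of their value, 94 moved further and none turned.

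The counts by the 2-fold rule moved with the threshold, with low genes and with symbols that have several rows. Against 130 higher symbols, there were 58 with a pseudocount of 5 FPKM, 64 at a mean FPKM of at least 5, 53 among protein-coding symbols with 1 row, 341 at 1.5-fold and 57 at 3-fold. Against 50 lower symbols, there were 79 with a pseudocount of 0.1 FPKM, 18 with 5 FPKM, 82 with no filter, 18 at a mean FPKM of at least 5, 20 among symbols with 1 row, 5 among protein-coding ones, 121 at 1.5-fold and 31 at 3-fold. For the pseudocounts, filters and thresholds this follows from their construction. Fewer symbols pass a stricter filter or threshold, and more low symbols pass a looser one. The drops among symbols with 1 row have another source. Symbols with several rows were 43 of the 130 higher and 30 of the 50 lower, but only 3.39% of those past the filter. Short RNA names with 1 row were another 20 of the higher and 13 of the lower symbols. Among the scalings, rescaling to a fixed sum gave 163 higher and 64 lower, and doing so without the abundant genes 160 and 73. With the pseudocount kept at 1 both settings also weigh low genes more. The summed FPKM were close, 422004 in KO and 425814 in WT, so for the fixed sum scaling can account for little of the move. Without the abundant genes the part due to scaling was not separated. The median of all genes moved by less than 0.1.

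Among the lists with small differences, several lost their place outside the random range, and the cause was not tested. Monocyte and neutrophil chemokines turned to -0.0468 with no filter and stood at 0.373, inside the range, as a mean. As means, T cell inhibitory molecules came to -0.00634, toll-like sensors to 0.134, the unfolded protein response to 0.0893, macrophage identity to -0.0238 and sex-linked genes to 0.403. T cell inhibitory molecules stood at -0.102 with a pseudocount of 0.1 FPKM, and the unfolded protein response at 0.0656 with 5 FPKM. At a mean FPKM of at least 5, alternative activation stood at -0.0956 and hypoxia at -0.119; without symbols with several rows alternative activation stood at -0.0793. Depth limits the low genes most: near 1 FPKM a gene of 1 kb rests on an estimated 34.8 reads in KO and 45.5 in WT.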

Other observations

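Families of interferon-inducible genes that reach beyond the lists were also higher in the KO library. They were singled out after their values were seen. All 11 expressed genes of the Ifi200 family on chromosome 1, which includes sensors of DNA, were higher in KO, 4 of them by the 2-fold rule, with a median difference of 0.94; 5 of them have several rows, and Ifi203, Ifi204 and Ifi211 stand in the type I list. Ifi208 stood at 16.1 FPKM in KO and 2.77 in WT (5.79-fold), Ifi206 at 34.1 and 7.66 FPKM, and Ifi213 at 54.4 and 14.5 FPKM. The 3 Phf11 genes had a median of 1.15 and the 5 Trim30 and Trim12 genes one of 0.77, higher in KO throughout; those medians are the values of Phf11b and Trim30a, which stand in the type I list. Ly6e, which blocks entry of some viruses, stood at 586.1 and 211.3 FPKM. Ifi27 went against its relative Ifi27l2a, at 36.3 FPKM in KO and 61.7 in WT.

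Members of 2 membrane protein families of myeloid cells, also singled out after their values were seen and set against no random lists, differed unevenly. Of 8 expressed Ms4a genes, Ms4a4c (3.63-fold) and Ms4a6b (2.29-fold, 124.9 against 54.4 FPKM) were higher in KO by the 2-fold rule, Ms4a4b (1.54-fold), Ms4a6c (1.52-fold) and Ms4a6d (1.32-fold) by less, while Ms4a4a (53.01 and 49.1 FPKM) and Ms4a14 (16.9 and 17.5 FPKM) were level. Of 8 expressed Cd300 genes, Cd300ld3 (4.78 against 1.68 FPKM) and Cd300ld4 (3.75 against 1.31 FPKM) were higher by the rule, and Cd300e (1.99 against 0.845 FPKM) and Cd300lf (1.64-fold) by less. The more abundant Cd300a (139.1 and 133.0 FPKM), Cd300lb (138.2 and 140.1 FPKM), Cd300ld (57.0 and 58.6 FPKM) and Cd300c2 (261.7 and 257.1 FPKM) were level.

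Of the tests that follow, the one on gene length and GC content was written before its result was seen; all others were chosen after. The interferon genes' place in the KO library was weighed first. Reads shared between repeated rows are argued against as its source for the 38 type I genes with 1 row, whose median was 1.18. Only 4 of the 42 genes have several rows, so leaving them out was bound to change the list's median little. Reads shared between different genes were not tested. With the trends of gene length or GC content removed, the lower of the 2 medians was 1.15, so neither trend is the whole of it. Dendritic cells in the KO culture stay open. In all, 6 of their markers summed to 0.934 FPKM in KO and 0.921 in WT, too near the floor to decide. Of the 4 listed dendritic genes past the filter, Bst2 (2.97-fold), Batf3 (1.55-fold) and Tcf4 (1.03-fold) were higher and Cd24a (0.913-fold) lower. Bst2 is itself in the type I list, so its difference cannot decide this. Loss of Spp1 may raise these genes. So could the Cre itself or the lower Lyz2, since only the KO mice carry the Cre. A difference between cultures could too, such as their share of less mature cells (monocyte markers had a median of 0.29, with F13a1 opposite at -1.35). The same holds for a difference between animals or in sex makeup (4 Y-linked genes summed to 20.6 FPKM in KO and 11.4 in WT). With 1 library per genotype these cannot be told apart.

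The extreme differences outside the interferon genes were weighed next. Of 47 symbols that differ by at least 2 outside Spp1 and the interferon lists, 38, or 80.9%, have several rows, which makes the handling of reads that fit several copies a candidate explanation. A plain move of reads from one row of a symbol to another is argued against: after summing the rows, the median size of the difference over the 38 was 2.81, and 37 stayed at 1 or more. Reads dropped as ambiguous in 1 library, or a strain variant near these genes in 1 of the animals, stay open and were not tested, since the reads were not used here. An effect of the genotype on these genes was not tested either.

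For Lyz2, a general lowering of abundant genes by the scaling is argued against by the other 50 symbols with the highest mean FPKM, whose median difference was 0.0799. The KO to WT ratio of Lyz2 was 0.459, while the 24 macrophage identity genes other than Lyz2 and Lyz1 had a median ratio of 0.969. Those values are consistent with loss of the transcript from 1 of 2 alleles, as a Cre inserted at Lyz2 might cause in mice with 1 copy of it; the labels do not give the number of copies. The lower level of Lyz1 (13.6 against 25.1 FPKM) could come from Lyz2 reads assigned to its paralog, which was not tested, and a direct effect of Spp1 loss on either gene stays open.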
